A study of Arabidopsis thaliana with 12 samples.

How the data were processed

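The series holds 12 Affymetrix ATH1 arrays of 4-day-old seedlings grown on agar under 16 h light and 8 h dark, with 3 biological replicates of Col-0, sco3, phyb and sco3phyb. The deposited values are log2 RMA expression per probe set, normalized across the 12 arrays by the authors. RMA and Partek are named per the submitters' processing notes, and their versions, background settings and any other software are not given in the sources used here. The values as deposited were used without a further transformation, after a check that their range, from 1.44 to 13.5, is that of log2 values. Arrays give no read depth, and signals near the lowest values carry no detection call. Replicates were taken from the sample titles, and no batch or date is given.

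Of 22810 probe sets, the 64 control probe sets were left out and 22746 were tested. The annotation gave 1 gene to 13513 probe sets (59.4%), several genes to 503 and none to 8730, so 13356 distinct genes could be named and the rest were tested without a name. Gene positions and neighbours were taken from the TAIR10.1 annotation. One linear model in limma 3.58.1 (R 4.3.3, with version 1.17.8 of the package data.table) was fitted to all 12 arrays with a mean per genotype, which leaves 8 residual degrees of freedom, and lmFit and eBayes were used for 5 pairwise contrasts and the interaction, sco3phyb minus phyb less sco3 minus Col-0. P-values are two-sided and were adjusted by Benjamini-Hochberg within each contrast, and a probe set was called at an adjusted p under 0.05. Standard errors of log2 differences are the moderated ones of this fit: their spread is pooled over all genotypes and drawn towards that of other probe sets. They are thus not the errors of the compared genotypes alone, which can be larger or smaller. The pipeline was tested on simulated data: with 67 genes changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold, 28.4%, 95.5% and 100% were recovered and 8 of 157 calls were false.

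Named genes followed a rule: 1 probe set per gene, called, with no overlap between the 3 values of each genotype in a pairwise contrast, the 8 largest rises and the 8 largest falls, and up to 4 called members of each gene list, or its best expressed members where none was called. The comparisons, tests, named-gene rule, fixed gene lists and alternatives named at the start were chosen before the data were examined. The 30 lists fixed then held 505 memberships, of which 121 could be named. These 15 lists with at least 3 named members were tested: light-harvesting antenna (3), nuclear photosynthetic electron transport (5), plastid-encoded photosynthesis (25), plastid-encoded NDH complex (10), plastid-encoded gene expression and housekeeping (21), Calvin cycle (4), tetrapyrrole and chlorophyll synthesis (9), plastid ribosomal proteins (6), shade-induced genes (4), early auxin response (4), cell wall expansion (5), flavonoids and anthocyanins (6), beta-oxidation and glyoxylate cycle (3), photorespiration (4) and stomatal lineage (3). Carotenoid synthesis and root hair cells had 2 named members, and plastid transcription, light signalling, acute stress, clock and jasmonate had 1. The remaining 8 fixed lists had none, among them the markers of 3 of the 5 cell type lists, so these cell types were not followed. A further 16 lists of families and pathways were written after the annotation was seen and before any expression value was tested, 15 of them with enough members, and 2 were written after the tests were seen (seed maturation and branched-chain amino acid catabolism).

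Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 90 tests for the fixed lists, 90 for the added lists and 12 for the last 2 lists. Camera called 29, 27 and 8 of them, and with a correlation estimated from the data it called 0, 0 and 0, with 8, 11 and 1 at an unadjusted p under 0.05. Fry, which asks whether a list moves on balance one way without comparing it with other genes, called 38, 39 and 5. Counts adjusted over the list alone use the members of that list as the family. Slopes through the origin compare contrasts that share no array, and 100 additive data sets were simulated by each of 2 rules as the reference, 1 of these rules and the reverse selection being chosen after the data were seen. Alternatives tried were array weights, a mean and variance trend with robust fitting, centring each array on its median, a further quantile normalization, leaving out the dimmest 40% of probe sets, the replicate number as a block, fitting 2 genotypes alone and leaving out each array in turn. Leaving out the 300 measured genes on each side of SCO3, and counting list members under each scaling, were added after the data were seen. Camera on simulated data gave 4 of 31 unshifted lists an unadjusted p under 0.05. Figures were drawn from the result tables.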

Results

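Transcript levels were measured on Affymetrix ATH1 arrays in whole Arabidopsis seedlings that were 4 days old. The 12 arrays covered 4 genotypes with 3 biological replicates each: the reference line Col-0, the single mutants sco3 and phyb, and the double mutant sco3phyb. PHYB encodes phytochrome B, a receptor for red and far-red light, and SCO3 (SNOWY COTYLEDON 3) encodes a protein needed for normal chloroplast development in cotyledons. According to its title, the series asks how the pathways of these genes act on each other in development and in the making of chloroplasts. The median log2 signal lay between 4.53 and 4.74 on the 12 arrays. The number of arrays limits the precision of every value, and the p-values measure the spread between the labelled biological replicates, pooled over the 4 genotypes. The probe annotation named neither SCO3 nor PHYB for any probe set, so the transcripts of these genes were not analysed here.

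**Figure D1:**
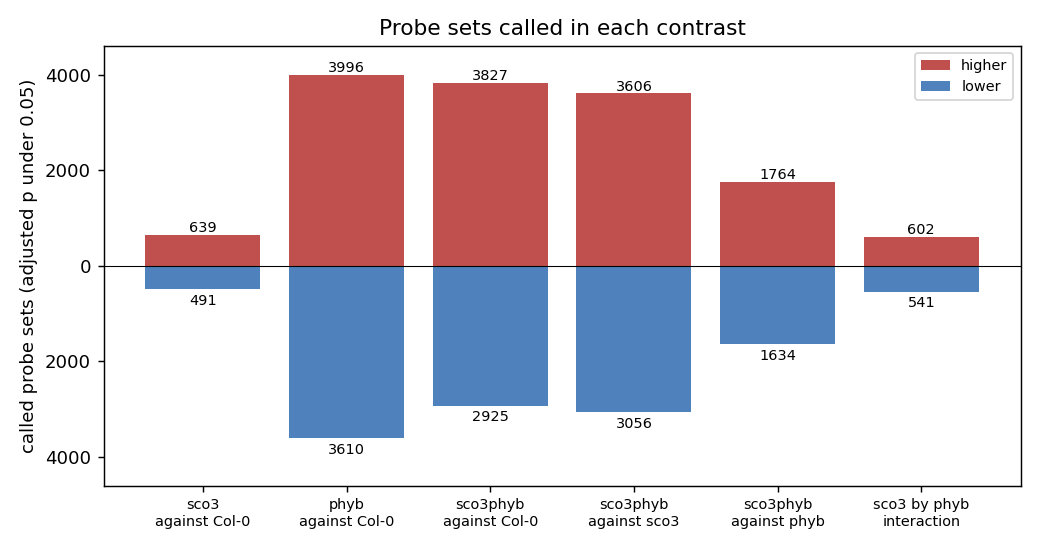
Number of probe sets called higher (red) or lower (blue) in each contrast, out of 22746 tested, at an adjusted p under 0.05. The sco3 comparison with Col-0 has 639 higher and 491 lower probe sets, and the phyb comparison has 3996 and 3610.

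The comparison of sco3 with Col-0 addressed what the sco3 mutation changed where PHYB was intact. Nuclear genes for chloroplast assembly and pigment synthesis were among those that rose. GSA1 (AT5G63570), an enzyme of early tetrapyrrole synthesis, rose by 0.81 ± 0.15 on the log2 scale (moderated standard error, n = 3 arrays per genotype, adjusted p = 0.0105). CRR28 (AT1G59720) and CRR41 (AT1G51100), both needed for the chloroplast NDH complex, rose by 0.95 ± 0.16 and 0.89 ± 0.15 (adjusted p from 0.00724 to 0.00755). The plastid gene psbK, for a small subunit of photosystem II, fell by 0.79 ± 0.12 on the log2 scale (adjusted p = 0.00482). The largest fall among named genes was that of AT3G19515, from 6.44 ± 0.10 in Col-0 to 3.35 ± 0.20 in sco3 (log2 signal, SD, n = 3, adjusted p = 9.67e-06). AT3G19515 lies in the stretch of the 600 measured genes nearest to SCO3 on chromosome 3, where 55 genes were called, or 9.17% against 4.35% elsewhere.

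Of the 9 measured genes of tetrapyrrole and chlorophyll synthesis, 1 rose over all genes tested and 4 rose when adjusted over the list alone. Their median was 0.29 and the list stood above other genes (camera adjusted p = 0.00365, and adjusted p = 0.638 with an estimated correlation). Fry gave 0.0517 for it. None of the 6 measured plastid ribosomal protein genes was called, adjusted over the list alone included, although their median of 0.28 passed the list test (camera adjusted p = 0.028, and adjusted p = 0.642 with an estimated correlation). Without Col-0 replicate 3 or sco3 replicate 2 that adjusted p was 0.265 or 0.0741. Fry gave 0.0997. In the early auxin response list, 0 of 4 genes were called and 2 fell when adjusted over the list alone (camera adjusted p = 0.0205, and adjusted p = 0.473 with an estimated correlation), with an adjusted p of 0.0903 without sco3 replicate 2. The plastid-encoded photosynthesis genes had a median of -0.13 with 1 of 25 lower, also 1 when adjusted over the list alone (camera adjusted p = 0.0433, and adjusted p = 0.707 with an estimated correlation). That list test gave 0.537, 0.151, 0.332 and 0.110 without Col-0 replicate 1, Col-0 replicate 2, sco3 replicate 2 and sco3 replicate 3. It gave 0.0537 after a further quantile normalization and 0.126 with the dimmest 40% of probe sets left out. Fry gave 0.449. The cell wall list held XTH19 (AT4G30290), a xyloglucan-modifying enzyme, which fell by 0.77 ± 0.16 on the log2 scale (adjusted p = 0.0178, and 0.0644 without sco3 replicate 1). In that list 2 of 5 genes fell, and adjusted over the list alone 2 fell and 1 rose, without a call for the list (camera adjusted p = 0.14).

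Other large rises were those of AT5G42760, by 2.03 ± 0.34, and of AT3G16175, which lies in the stretch around SCO3, by 1.94 ± 0.20 (adjusted p from 6.35e-04 to 0.00663). Among the falls, AT3G13610, a hydroxylase of coumarin synthesis, fell by 1.93 ± 0.27 and the peroxidase gene AT3G21770, which lies in that stretch, fell by 1.83 ± 0.22 on the log2 scale (adjusted p from 0.00132 to 0.00318). In total 1130 of 22746 probe sets were called, 639 higher and 491 lower, and 263 of them differed by at least 2-fold. Centring each array on its median moved the share of higher calls from 56.5% to 67.4%. The median array signal differed by -0.05 between sco3 and Col-0, and the median change over probe sets was 0.02. Col-0 replicate 3 stood apart, with a mean correlation of 0.978 with its group across probe sets, which are not independent replicates, against 0.986 for each of the other Col-0 arrays. Without it 859 probe sets were called, 689 of them among the 1130. The 1130 calls rest on a spread pooled over all 4 genotypes. The mean absolute residual was larger in the Col-0 arrays (0.149 to 0.214) than in those of phyb and sco3phyb (0.0949 to 0.121). The count depended on the arrays fitted and was 117 when only the Col-0 and sco3 arrays were fitted, with 115 of these among the 1130. It was 488, 526 and 396 without sco3 replicates 1, 2 and 3, and 745 without sco3phyb replicate 3.

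The comparison of phyb with Col-0 addressed what the phyb mutation changed where SCO3 was intact. Plastid genes for photosynthesis were lower in phyb. petG, a subunit of the cytochrome b6f complex, fell by 4.52 ± 0.29 on the log2 scale, from 8.73 ± 0.42 to 4.21 ± 0.35 (log2 signal, SD, n = 3). psaC and psaJ of photosystem I fell by 3.74 ± 0.29 and 2.51 ± 0.20, and psbH of photosystem II fell by 2.38 ± 0.23 (adjusted p for the 4 genes from 2.68e-07 to 7.30e-06). Of the 5 measured cell wall expansion genes 4 were higher, and IAA29 (AT4G32280), an auxin-induced regulator of the shade list, rose by 2.17 ± 0.31. The expansin genes EXPB1 (AT2G20750) and EXPA8 (AT2G40610) rose by 2.35 ± 0.17 and 1.99 ± 0.22 (adjusted p for the 3 genes from 7.43e-07 to 1.57e-04). Of the 28 measured expansin and xyloglucan endotransglucosylase genes, 9 rose and 6 fell, without a call for that list (camera adjusted p = 0.0642). Its median of 0.14 was -0.00260 with each array centred on its median.

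Of the 25 plastid-encoded photosynthesis genes, 18 fell and 0 rose, or 18 and 1 adjusted over the list alone, and their median was -0.91 (camera adjusted p = 1.81e-05, and adjusted p = 0.604 with an estimated correlation). The plastid-encoded NDH complex followed with 6 of 10 genes lower, 8 adjusted over the list alone, among them ndhG, which fell by 2.51 ± 0.27, and ndhE, which fell by 2.40 ± 0.23 (median -0.55, camera adjusted p = 0.00182, and adjusted p = 0.606 with an estimated correlation). In the plastid list of gene expression and housekeeping, 11 of 21 genes fell, 12 adjusted over the list alone (median -0.61, camera adjusted p = 0.00149, and adjusted p = 0.642 with an estimated correlation). Its largest falls were those of the ribosomal protein gene rpl20, by 2.96 ± 0.32, and of accD, for a subunit of acetyl-CoA carboxylase, by 1.95 ± 0.25. Of the nuclear plastid ribosomal protein genes 4 of 6 fell, 4 adjusted over the list alone, among which AT4G01310 fell by 0.65 ± 0.15, with no call for the list (camera adjusted p = 0.0622). Tetrapyrrole synthesis was split, with 5 of 9 genes lower and 2 higher, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.175). CHLM (AT4G25080), a methyltransferase of chlorophyll synthesis, fell by 0.60 ± 0.13, and PORB (AT4G27440), a light-dependent protochlorophyllide reductase, rose by 1.03 ± 0.25 (adjusted p from 0.00252 to 0.00673). LHCB4.2 (AT3G08940), a minor antenna protein of photosystem II, fell by 0.62 ± 0.10 as the called gene among 3 antenna genes, also 1 when adjusted over the list alone (camera adjusted p = 0.571).

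Of the 4 measured shade-induced genes 3 rose, also 3 adjusted over the list alone: IAA29, the homeodomain gene HAT2 (AT5G47370) by 1.38 ± 0.20 and FHL (AT5G02200), which helps import phytochrome A into the nucleus, by 0.95 ± 0.23 (camera adjusted p = 0.0192, and adjusted p = 0.48 with an estimated correlation). With the dimmest 40% of probe sets left out the shade-induced list was not called (adjusted p = 0.136). The cell wall list had 4 of 5 genes higher, also 4 adjusted over the list alone, with EXPA4 (AT2G39700) up by 0.99 ± 0.22 (camera adjusted p = 0.00103, and adjusted p = 0.194 with an estimated correlation). GH3.3 (AT2G23170), an auxin-conjugating enzyme, rose by 1.16 ± 0.19. Early auxin genes, a list that shares IAA29 with the shade-induced list, had 2 of 4 higher, 3 adjusted over the list alone (camera adjusted p = 0.0484, and adjusted p = 0.473 with an estimated correlation). That list test gave 0.0855, 0.0627, 0.0623, 0.0546 and 0.0644 without Col-0 replicates 1 and 2, sco3 replicates 2 and 3 and phyb replicate 2. It gave 0.0537 after a further quantile normalization and 0.0908 with the dimmest probe sets left out. Flavonoid and anthocyanin genes also rose, 4 of 6, or 5 adjusted over the list alone, with a median of 1.19 (camera adjusted p = 8.07e-04, and adjusted p = 0.473 with an estimated correlation). UGT78D1 (AT1G30530), a flavonol rhamnosyltransferase, rose by 1.88 ± 0.16 and DFR (AT5G42800), a reductase of anthocyanin synthesis, rose by 1.59 ± 0.26 (adjusted p from 2.22e-06 to 4.07e-04).

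The largest rise in phyb among named genes was that of GH9B8 (AT2G32990), of the family of plant cellulases, by 4.81 ± 0.18, and the expansin gene EXPB3 (AT4G28250) rose by 3.94 ± 0.33 (adjusted p from 7.34e-09 to 2.30e-06). MCCA (AT1G03090), a subunit of the methylcrotonyl-CoA carboxylase of leucine breakdown, fell by 4.02 ± 0.20 on the log2 scale (adjusted p = 4.05e-08). AT3G55920 fell by 4.51 ± 0.12 to 1.98 ± 0.05, near the lowest values on the arrays, and stood at 6.54 ± 0.17 in sco3phyb (log2 signal, SD, n = 3). In total 7606 probe sets were called, 3996 higher and 3610 lower, 1994 of them by at least 2-fold. The median array signal was higher by 0.15 in phyb than in Col-0 on the log2 scale, and relative to that shift the share of higher calls was 30.9% in place of 52.5%. The median change over probe sets was -0.06 as deposited, so the typical probe set did not rise. Centring is thus an alternative scaling and not a correction.

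Lists with fewer measured genes were also read in phyb. AT1G80380, for glycerate kinase, fell by 1.19 ± 0.13 as 1 of 4 photorespiration genes, also 1 adjusted over the list alone (camera adjusted p = 0.436). SDP1 (AT5G04040), a lipase of seed oil breakdown, fell by 1.75 ± 0.11, and ICL (AT3G21720), the isocitrate lyase of the glyoxylate cycle, rose by 1.17 ± 0.37 (adjusted p = 0.0266, and 0.102, 0.0941, 0.0963 and 0.110 without Col-0 replicates 1 and 2 and phyb replicates 2 and 3). These were 1 fall and 1 rise among 3 genes of fatty acid beta-oxidation and the glyoxylate cycle, the same counts adjusted over the list alone (camera adjusted p = 0.703). FMA (AT3G24140), a regulator of guard cell formation, fell by 0.89 ± 0.17 as 1 of 3 genes of the stomatal lineage, also 1 adjusted over the list alone (camera adjusted p = 0.303). PSBW (AT2G30570), a photosystem II subunit, fell by 0.33 ± 0.10 as 1 of 5 nuclear genes of electron transport, also 1 adjusted over the list alone (camera adjusted p = 0.663, adjusted p for PSBW 0.0621 and 0.0683 without phyb replicates 1 and 3). With each array centred on its median 3 of these 5 genes fell, and 2 of the 4 photorespiration genes. Among 4 genes of the Calvin cycle, AT1G56190, for phosphoglycerate kinase, differed by 0.50 ± 0.18 with an adjusted p of 0.0478, which was 0.135 after centring each array and between 0.0537 and 0.121 when any 1 array other than Col-0 replicates 1 and 2 was left out. No Calvin cycle gene passed adjusted over the list alone, and the list was not called (camera adjusted p = 0.303). Single measured members stood for several lists. HYH (AT3G17609), a light-signalling transcription factor whose gene lies in the stretch around SCO3, rose in sco3 by 1.11 ± 0.23 (adjusted p = 0.0205, and 0.0696, 0.0534 and 0.0641 without sco3 replicates 1, 2 and 3) and differed by 0.36 ± 0.23 in phyb. The clock gene GI (AT1G22770) rose in sco3phyb against Col-0 by 1.45 ± 0.29 (adjusted p = 0.00227). AT5G15700, for an organellar RNA polymerase, differed by -0.03 ± 0.13 in phyb, the defensin gene PDF1.2 by -0.03 ± 0.13 and the stress regulator STZ by 0.44 ± 0.34, none of them called. Of the carotenoid genes, LYC differed by 0.24 ± 0.17 and Z-ISO by 0.14 ± 0.12, and of the root hair markers EXPA7 by 0.34 ± 0.37 and EXPA18 by 0.65 ± 0.38, again without a call.

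**Figure D2:**
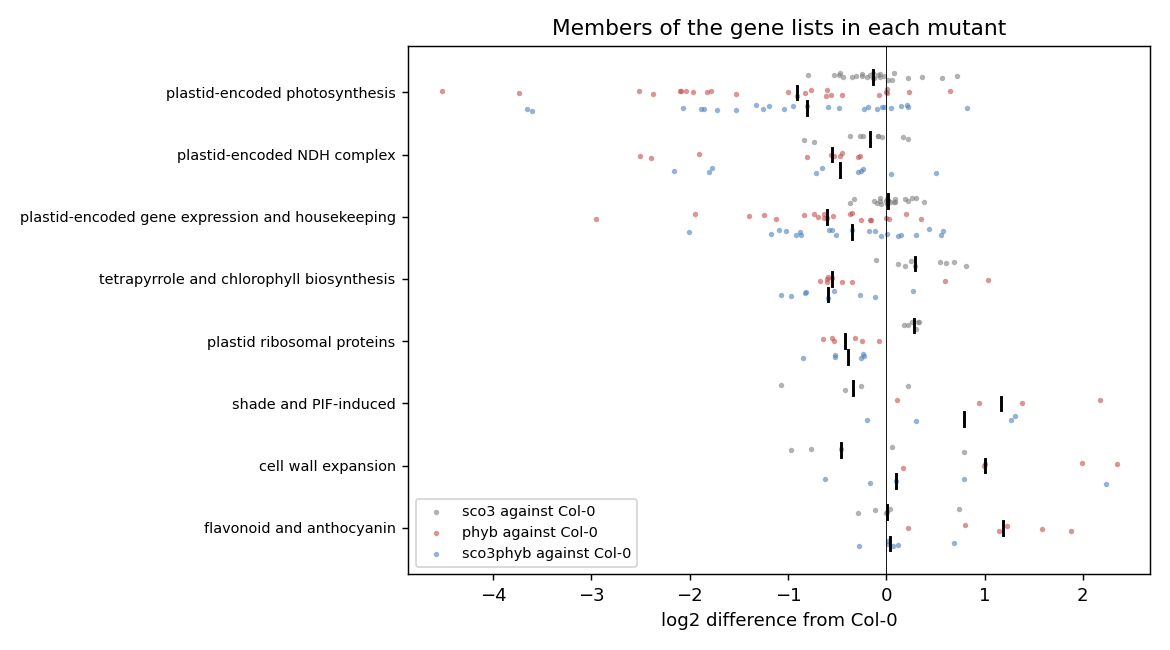
Log2 difference from Col-0 of each measured member (points) of 8 gene lists, with the list median as a black bar, in sco3 (grey), phyb (red) and sco3phyb (blue), as deposited. The plastid-encoded photosynthesis median was -0.91 in phyb and -0.80 in sco3phyb. The flavonoid median was 1.19 in phyb and 0.04 in sco3phyb, the latter -0.09 with each array centred on its median, and the cell wall median of 0.10 in sco3phyb was -0.02 with that centring.

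The double mutant was compared with Col-0 to show the combined change. Plastid photosynthesis genes were again lower: psaC fell by 3.66 ± 0.29 on the log2 scale, and petG fell from 8.73 ± 0.42 to 5.13 ± 0.52 (log2 signal, SD, n = 3, adjusted p from 2.49e-06 to 2.82e-06). QQS (AT3G30720), a gene that affects how seedlings divide carbon between starch and protein, fell by 4.41 ± 0.11, from 8.25 ± 0.06 to 3.84 ± 0.11 (log2 signal, SD, n = 3, adjusted p = 2.46e-10). UGT84A3 (AT4G15490), a glucosyltransferase, rose by 4.52 ± 0.23, and EXPA8 rose by 2.24 ± 0.22 (adjusted p from 9.31e-08 to 1.46e-05). On chromosome 5, CSA1 (AT5G17880), for a disease resistance receptor, fell by 3.37 ± 0.14 and AT5G23830 fell by 4.33 ± 0.25 (adjusted p from 2.15e-08 to 2.27e-07). Both lay below the lower quartile of every array in sco3phyb, at 2.31 ± 0.20 and 2.51 ± 0.12, and were not shown to be above background there.

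In sco3phyb against Col-0, 12 of 25 plastid-encoded photosynthesis genes fell and 1 rose, or 14 and 1 adjusted over the list alone (camera adjusted p = 9.69e-05, and adjusted p = 0.642 with an estimated correlation). The NDH list had 5 of 10 genes lower, 7 adjusted over the list alone (camera adjusted p = 0.00839, and adjusted p = 0.642 with an estimated correlation), and ndhE fell by 2.16 ± 0.23. In the plastid list of gene expression and housekeeping 9 of 21 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0369, and adjusted p = 0.707 with an estimated correlation). The list test gave 0.176, 0.0690 and 0.123 without Col-0 replicate 1, Col-0 replicate 2 and sco3phyb replicate 2, and 0.0537 after a further quantile normalization. Fry gave 0.119 for it. Tetrapyrrole genes had 6 of 9 lower, also 6 adjusted over the list alone (camera adjusted p = 0.00778, and adjusted p = 0.642 with an estimated correlation). Among them HEME2 (AT2G40490), a uroporphyrinogen decarboxylase, fell by 1.07 ± 0.18 and HEMB1 (AT1G69740), a porphobilinogen synthase, fell by 0.97 ± 0.15 (adjusted p from 3.56e-04 to 7.90e-04). Plastid ribosomal protein genes had 3 of 6 lower, also 3 adjusted over the list alone (camera adjusted p = 0.0238, and adjusted p = 0.642 with an estimated correlation), with 0.0731 and 0.0728 without Col-0 replicates 1 and 2. With each array centred on its median 5 of these 6 fell. LHCB4.2 and LHCB4.3 (AT2G40100) fell by 0.97 ± 0.10 and 0.91 ± 0.22 among 3 antenna genes, both also adjusted over the list alone (camera adjusted p = 0.0504). IAA29 and HAT2 rose by 1.27 ± 0.31 and 1.31 ± 0.20 among 4 shade-induced genes, both also adjusted over the list alone (camera adjusted p = 0.133). In total 6752 probe sets were called, 3827 higher and 2925 lower, 1727 of them by at least 2-fold. Relative to a shift of 0.13 in the median array signal the share of higher calls was 36.6% in place of 56.7%, while the median change over probe sets was -0.02.

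Setting sco3phyb against sco3 addressed the change made by the phyb mutation where sco3 was already present. Any other difference between these lines would also appear in it. Of the 9 tetrapyrrole genes, 7 were lower: HEME2 fell by 1.61 ± 0.18, HEME1 (AT3G14930) by 1.52 ± 0.23, CHLI2 (AT5G45930), of the magnesium chelatase, by 1.42 ± 0.18, and HEMB1 by 1.26 ± 0.15 (adjusted p from 4.07e-05 to 3.55e-04). psaC fell by 3.35 ± 0.29 and petG by 3.07 ± 0.29, while IAA29 rose by 2.34 ± 0.31 and EXPA8 by 2.70 ± 0.22 (adjusted p from 3.46e-06 to 1.20e-04). ICL fell by 1.81 ± 0.37 and SDP1 by 1.15 ± 0.11, which were 2 falls among 3 genes of beta-oxidation and the glyoxylate cycle, also adjusted over the list alone (camera adjusted p = 0.104). The tetrapyrrole list had 7 of 9 genes lower, 8 adjusted over the list alone, with a median of -0.78 (camera adjusted p = 6.84e-05, and adjusted p = 0.48 with an estimated correlation). All 6 measured plastid ribosomal protein genes fell, also adjusted over the list alone, with a median of -0.66 (camera adjusted p = 0.00103, and adjusted p = 0.577 with an estimated correlation), and 5 fell after a further quantile normalization. Among plastid-encoded photosynthesis genes 11 of 25 fell and 2 rose, or 14 and 2 adjusted over the list alone (camera adjusted p = 0.00196, and adjusted p = 0.642 with an estimated correlation). With each array centred on its median 16 fell and 1 rose. The shade-induced list had 2 of 4 higher, 3 adjusted over the list alone (camera adjusted p = 0.0461, and adjusted p = 0.577 with an estimated correlation). It gave 0.0549, 0.0563, 0.0818, 0.0546 and 0.0518 without Col-0 replicates 1 and 3, sco3 replicates 1 and 3 and phyb replicate 2, and 0.0540 after a further quantile normalization. In the plastid gene expression list 11 of 21 fell, and adjusted over the list alone 11 fell and 1 rose (camera adjusted p = 0.0238, and adjusted p = 0.698 with an estimated correlation). The test gave 0.105 and 0.0903 without sco3 replicate 1 and sco3phyb replicate 2, and fry gave 0.0896. Early auxin genes, a list that shares IAA29 with the shade-induced list, had 3 of 4 higher, also 3 adjusted over the list alone (camera adjusted p = 0.0437, and adjusted p = 0.473 with an estimated correlation). Their adjusted p was 0.0553, 0.106 and 0.0546 without Col-0 replicate 1 and sco3 replicates 2 and 3, 0.0537 after a further quantile normalization and 0.0661 with the dimmest probe sets left out. With each array centred on its median, or after that quantile normalization, 2 of the 4 rose. No flavonoid gene of 6 was called, adjusted over the list alone included (camera adjusted p = 0.875). In total 6662 probe sets were called, 3606 higher and 3056 lower, 1550 of them by at least 2-fold. Relative to a shift of 0.17 in the median array signal the share of higher calls was 26.4% in place of 54.1%, while the median change over probe sets was -0.04.

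Setting sco3phyb against phyb addressed the change made by the sco3 mutation where phyb was already present. Any other difference between these lines would also appear in it. Flavonoid genes were lower: UGT78D1 fell by 1.81 ± 0.16, DFR by 1.47 ± 0.26 and AT4G14090, an anthocyanin glucosyltransferase, by 1.12 ± 0.24 on the log2 scale (adjusted p from 1.09e-05 to 0.00712). AT4G14090 lay below the lower quartile of every array in sco3phyb. Cell wall genes were lower too, with EXPB1 down by 1.55 ± 0.17 and XTH19 by 1.17 ± 0.16 (adjusted p from 7.27e-05 to 2.88e-04). FHL fell by 1.14 ± 0.23 as 1 of 4 shade-induced genes and GH3.3 by 1.03 ± 0.19 as 1 of 4 early auxin genes, 2 in each list adjusted over the list alone, and neither list was called (camera adjusted p = 0.135 and 0.0622). PORB fell from 8.95 ± 0.28 in phyb to 7.64 ± 0.54 in sco3phyb (log2 signal, SD, n = 3), and BCAT4 (AT3G19710), an aminotransferase of glucosinolate synthesis, fell by 3.13 ± 0.19 on the log2 scale (adjusted p from 6.22e-07 to 0.00385). Of the 47 measured genes of the UDP-glycosyltransferase family, 8 rose and 6 fell, without a call for the list (camera adjusted p = 0.278), with UGT73C1 (AT2G36750) up by 2.88 ± 0.20, UGT84A3 by 2.82 ± 0.23 and UGT73B1 (AT4G34138) by 2.73 ± 0.19 (adjusted p from 1.63e-06 to 6.68e-06).

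In this comparison 5 of 6 flavonoid genes fell, 6 adjusted over the list alone, with a median of -0.96 (camera adjusted p = 2.09e-05, and adjusted p = 0.473 with an estimated correlation). The cell wall list had 4 of 5 genes lower, also 4 adjusted over the list alone (camera adjusted p = 0.00103, and adjusted p = 0.194 with an estimated correlation). Antenna genes had 2 of 3 lower, also 2 adjusted over the list alone (camera adjusted p = 0.0433, and adjusted p = 0.48 with an estimated correlation). Their adjusted p was 0.0544, 0.0790, 0.0517 and 0.0557 without sco3 replicate 2, phyb replicates 1 and 2 and sco3phyb replicate 1, 0.0540 after a further quantile normalization and 0.106 with the dimmest probe sets left out. With each array centred on its median 1 of the 3 fell. Plastid-encoded photosynthesis genes had 3 of 25 higher and 2 lower, or 5 and 2 adjusted over the list alone, and were not called as a list (camera adjusted p = 0.112). Among them psbK fell by 0.97 ± 0.12 (adjusted p = 2.17e-04). In total 3398 probe sets were called, 1764 higher and 1634 lower, 740 of them by at least 2-fold. The count was 6505 with array weights, 2218 and 2261 without phyb replicates 2 and 3, and 2243 without sco3phyb replicate 3.

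The interaction contrast asked whether the sco3 change differed between phyb and PHYB backgrounds. A difference carried by 1 line alone for another reason would also appear in it. ICL, which lies in the stretch around SCO3 where sco3 calls were more frequent, had an interaction of -2.98 ± 0.52: it rose by 1.49 ± 0.37 in sco3 against Col-0 and fell by 1.48 ± 0.37 in sco3phyb against phyb (log2, standard error, interaction adjusted p = 0.006). The sco3 rise of ICL had an adjusted p of 0.0376 and lay between 0.0502 and 0.126 when 1 of 8 arrays was left out, namely Col-0 replicates 1 and 2, the 3 sco3 replicates, phyb replicate 2 and sco3phyb replicates 2 and 3. Its fall against phyb had adjusted p of 0.0705, 0.0760 and 0.0701 without phyb replicates 2 and 3 and sco3phyb replicate 1. GSA1 had an interaction of -1.13 ± 0.21, UGT78D1 of -1.82 ± 0.22, UGT78D2 (AT5G17050), a flavonoid glucosyltransferase, of -1.28 ± 0.21, EXPB1 of -1.60 ± 0.24 and BCAT4, also in that stretch, of -3.19 ± 0.27 (adjusted p from 4.84e-05 to 0.00782). AT3G55920 and UGT73C1 had positive interactions of 4.63 ± 0.16 and 2.80 ± 0.28 (adjusted p from 1.98e-08 to 1.28e-04). Their signals in phyb, 1.98 ± 0.05 and 2.55 ± 0.06, were below the lower quartile of every array and not shown to be above background, so these sizes are differences between measured signals.

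Among the lists, flavonoid genes had a median interaction of -1.17, with 2 of 6 called lower and 4 adjusted over the list alone (camera adjusted p = 2.95e-05, and adjusted p = 0.473 with an estimated correlation). Tetrapyrrole genes had a median of -0.88, with 1 of 9 called lower and 6 adjusted over the list alone (camera adjusted p = 2.21e-04, and adjusted p = 0.532 with an estimated correlation). No plastid-encoded photosynthesis gene of 25 was called, adjusted over the list alone included, and their median was 0.39 (camera adjusted p = 0.00421, and adjusted p = 0.656 with an estimated correlation, and 0.0793 without Col-0 replicate 1). Fry gave 0.243. No plastid ribosomal protein gene of 6 was called either, adjusted over the list alone included, with a median of -0.28 (camera adjusted p = 0.041, and adjusted p = 0.642 with an estimated correlation). That list test gave 0.184, 0.0751, 0.0546, 0.0644 and 0.0622 without Col-0 replicate 3, sco3 replicates 2 and 3, phyb replicate 2 and sco3phyb replicate 1. It gave 0.0537 after a further quantile normalization and 0.0696 with the dimmest probe sets left out. Fry gave 0.180 for it. In total 1143 probe sets were called, 602 higher and 541 lower, 613 of them by at least 2-fold. The count was 1957 with array weights, 761 and 661 without phyb replicates 2 and 3, and 755 and 716 without sco3phyb replicates 2 and 3.

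Across the 1130 probe sets called in sco3 against Col-0, the sco3 change with phyb followed the change without it at a slope of 0.427. In sco3phyb against phyb, 328 of them were called in the same direction, 33 in the opposite direction and 769 were not called, where 84.8 would be called in the same direction at random. The interaction, adjusted over these probe sets alone, was called in 342 with a smaller change beside phyb and in 30 with a larger one. Choosing probe sets by the change in sco3 favoured a smaller second change by itself. Simulated data in which both mutations add on the log2 scale gave slopes from 0.794 to 0.820, or from 0.759 to 0.787 with another rule for the simulated effect, and called more probe sets (a median of 2954 and 2384) than were found. Under the first rule 1583 to 1750 were called in both with the same direction, and the interaction called at most 6 with a smaller and 1 with a larger change. Larger simulated effects are pulled less by this choice, and the noise was drawn for each probe set alone, without deviations shared across an array. The simulated slopes may thus be too high as a reference, and they cannot settle how much of the smaller slope came from the choice of probe sets. Selected in the other direction, over the 3398 probe sets called in sco3phyb against phyb, the slope was 0.176, for which no reference was simulated. For the phyb change the slope was 0.625 over 7606 probe sets, against simulated slopes from 0.917 to 0.929 and from 0.928 to 0.941, which carry the same limits. It was 0.791 when selected on the 6662 called in sco3phyb against sco3, again without a simulated reference. Of the 7606, 4103 were called in the same direction (1118.5 at random), 95 in the opposite direction and 3408 were not called. The interaction adjusted over them was called in 1253 with a smaller change beside sco3 and in 129 with a larger one. The simulated data of the first rule, with a median of 8053 called, had 5893 to 6216 called in both with the same direction and at most 2 smaller and 1 larger.

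**Figure D3:**
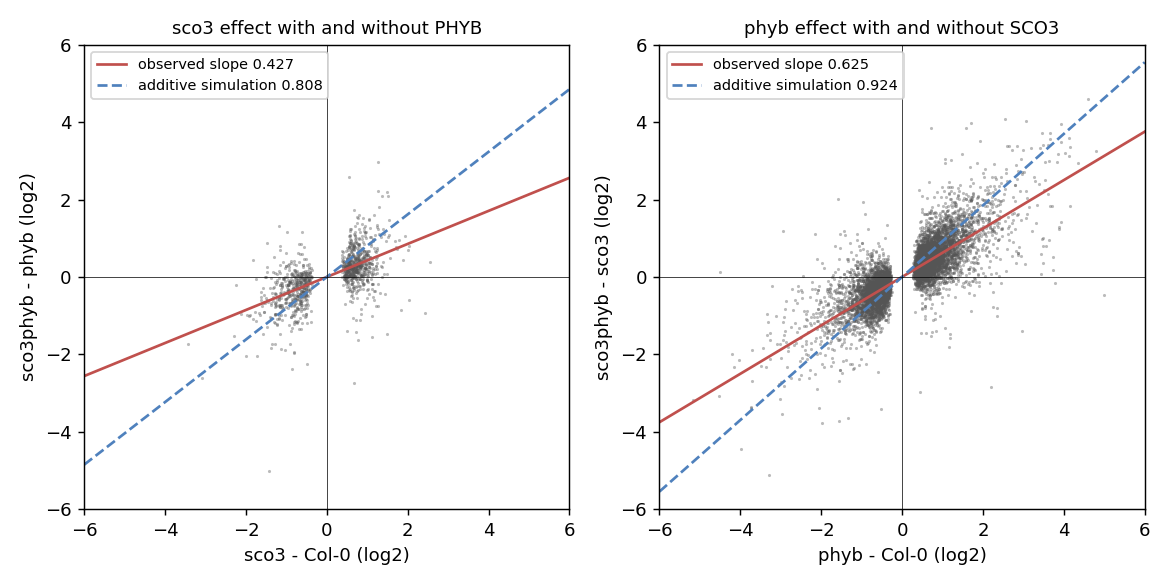
Left, log2 difference of sco3phyb from phyb against that of sco3 from Col-0, over the 1130 probe sets called in sco3 against Col-0. Right, log2 difference of sco3phyb from sco3 against that of phyb from Col-0, over the 7606 called in phyb against Col-0. Red lines are the slopes of 0.427 and 0.625, and dashed blue lines the median slopes of 0.808 and 0.924 in simulated additive data.

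Genes in which 1 genotype stood apart, called and at least 2-fold different in the same direction from each of the other 3, were also sorted by chromosome, which was chosen after the data were seen. In sco3phyb 72 named genes stood apart, 33 lower and 39 higher, and 35 of them lay on chromosome 5. CSA1 and AT5G23830 were 2 of these. In sco3, 16 of 33 such genes lay on chromosome 3, which also carries SCO3. By definition these genes differed from sco3phyb too, which carries the same mutation, so their place is not evidence of a segment shared by both lines. In phyb, 31 of 175 lay on chromosome 3 and 39 of 175 on chromosome 5.

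**Figure D4:**
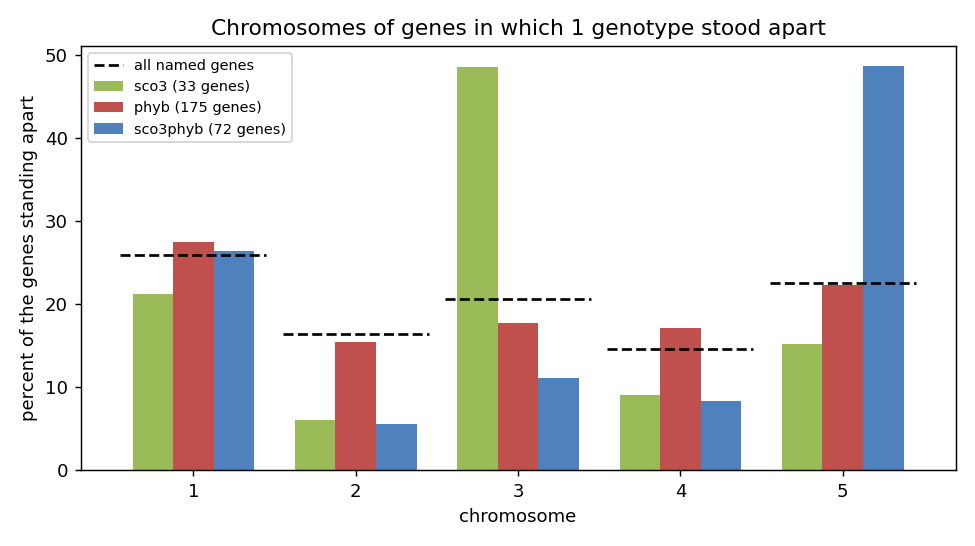
Percent of the named genes in which sco3 (green), phyb (red) or sco3phyb (blue) stood apart from each of the other 3 genotypes that lie on each chromosome, with the share of all named genes as dashed lines. Chromosome 5 held 35 of the 72 genes of sco3phyb, and chromosome 3 held 16 of the 33 genes of sco3.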

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

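The 6 counts of other splits were chosen before the data were examined, and the tests of chromosome position and of Col-0 replicate 3 were chosen only after those results were seen. The genes and lists of this paragraph and the next stood out because the sco3 change with phyb differed from the sco3 change without phyb in the interaction test, which called 1143 probe sets. The slopes stood out in another comparison, with simulated additive data: the sco3 change across phyb backgrounds had a slope of 0.427 and the phyb change across sco3 backgrounds 0.625, each below the simulated slopes. Those simulated slopes may be too high as a reference, for the reasons given with them. The positive interactions (log2) of the named genes, taken from the measured signals, were those of AT3G55920 (4.63), AT4G01870 (3.28), AT5G15360 (3.22), AT1G50290 (3.12), AT1G33055 (2.99), UGT73C1 (2.80), AT5G24240 (2.58) and AT5G61820 (2.56). The negative ones were those of CP1 (-5.05), AT2G47780 (-4.37), AT5G23830 (-3.58), PAP85 (-3.36), BCAT4 (-3.19), ICL (-2.98), CSA1 (-2.87) and AT5G04120 (-2.84). AT5G15360, AT5G24240, AT5G61820, AT5G23830 and CSA1 are chromosome 5 genes in which sco3phyb stood apart. PAP85, BCAT4 and ICL lie in the stretch around SCO3. AT3G55920 was low in phyb alone, at 1.98 against 6.42 to 6.54 in the other genotypes. A difference carried by 1 line alone, without any interaction, would give the same contrast. PAP85 had an adjusted p of 0.0527 without sco3phyb replicate 2. AT5G04120 had 0.0507 without Col-0 replicate 2, 0.0618, 0.0513 and 0.0584 without sco3 replicates 1, 2 and 3, 0.0693 without phyb replicate 3, and 0.0675 and 0.0719 without sco3phyb replicates 2 and 3.

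Gene lists stood out for the same reason, with a median interaction of 0.39 for plastid-encoded photosynthesis, -0.88 for tetrapyrrole synthesis, -0.28 for plastid ribosomal proteins and -1.17 for flavonoids. The lists added later had -0.28 for nuclear genes of thylakoid assembly and plastid RNA processing, 0.40 for autophagy, -0.47 for glucosinolates and -0.32 for cytosolic ribosomal proteins. Seed maturation had -0.62 and branched-chain amino acid catabolism 0.34. With an estimated correlation the adjusted p of these 10 lists lay between 0.2 and 0.759. At the preset correlation the thylakoid list had an adjusted p of 0.677, 0.0745 and 0.106 without Col-0 replicate 3, sco3 replicate 2 and sco3phyb replicate 1, and the autophagy list 0.0526 without Col-0 replicate 3. With the dimmest probe sets left out the thylakoid list had 0.0589, and fry gave 0.438 for it and 0.0670 for seed maturation. The plastid-encoded photosynthesis list had 0.0793 without Col-0 replicate 1, and the plastid ribosomal protein list 0.184, 0.0751, 0.0546, 0.0644 and 0.0622 without Col-0 replicate 3, sco3 replicates 2 and 3, phyb replicate 2 and sco3phyb replicate 1. Fry gave 0.243 for the former and 0.180 for the latter, which also had 0.0537 after a further quantile normalization and 0.0696 with the dimmest probe sets left out.

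The interaction count of 1143 was reached in 1 of 100 splits of the 12 arrays, the real one, and the highest other split called 851 probe sets. The other splits also mixed phyb arrays with arrays of other genotypes, so they are not a reference for the interaction alone. They argue against a random grouping of the arrays into genotypes and cannot decide whether the interaction calls arose at random. For the pairwise contrasts, the 10 splits of 6 arrays are too few for a share under 0.05. In each of them 1 split, the real one, gave as many calls: 1130 in sco3 against Col-0 with 0 as the highest other, 7606 in phyb against Col-0 with 27, 6752 in sco3phyb against Col-0 with 1, 6662 in sco3phyb against sco3 with 0 and 3398 in sco3phyb against phyb with 0.

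The genes called in sco3 against Col-0 lay together around SCO3: of the 600 measured genes nearest to it, 55 were called, 33 lower and 22 higher, which is 9.17% against 4.35% elsewhere. Placing the calls at random on the measured genes gave 18 to 38 in 95% of 10000 draws and never more than 48, which argues against random placement. A candidate explanation is a segment inherited with sco3 from other parental material: the slope of these 55 genes in sco3phyb against phyb was 0.515 (95% bootstrap interval 0.307 to 0.673) against 0.426 for called genes elsewhere, and the interval holds the value elsewhere. It also lies wholly below the slope set as the bar for this explanation, so a segment was not shown. That bar lay close to the slopes of simulated additive data over all calls (0.794 to 0.820, or 0.759 to 0.787 with the other rule). Any of the 55 genes called for another reason could keep the slope below it. The test thus cannot exclude a segment that accounts for part of the 55. Sequence variants that weaken probe binding also stay open, because 60% of the 55 were lower (exact 95% interval 45.9 to 73.0) against 41.9% elsewhere. That interval ends below the share set as the bar for this explanation, so it was not shown. An effect of sco3 on these genes themselves was not tested, and the neighbours of PHYB showed no such excess, with 25% called in phyb against 30.8% elsewhere.

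In sco3phyb, 35 of the 72 named genes standing apart lay on chromosome 5, where random placement gave 10 to 23 in 95% of 10000 draws and never more than 33. That argues against random placement of these genes. The draws placed each gene alone, so neighbours that change together were not allowed for, and the pattern was picked after the data were seen. Random placement stayed open for the fullest stretch of 100 measured genes, with 12 genes called by at least 2-fold against phyb, where the upper end of the 95% range of 1000 random draws was 10 and the highest draw was 13. Sequence variants that weaken probe binding may contribute to some of them: of the stretch 75% were lower (exact 95% interval 42.8 to 94.5), and of the 35 genes 57.1% (39.4 to 73.7). The share of the 35 genes was under the bound set against this explanation, but its interval held that bound. The same interval ended below the bound set for the explanation. Of the 35 genes, 20 were lower and 15 higher. Weaker binding in sco3phyb would not by itself give the 15 higher genes. The test cannot decide how many of the 20 lower genes it accounts for. The interval of the stretch held both bounds. A segment of other parental material that sco3phyb alone carries is a further candidate explanation and was not tested, and neither was a response of these genes to both mutations together.

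Col-0 replicate 3 stood apart from the other Col-0 arrays, with a mean correlation across genes, which are not independent replicates, of 0.978. After a further quantile normalization it was again 0.978, which argues against a difference in signal distribution, and its highest correlation with an array of another genotype was 0.969, below its lowest with Col-0 at 0.978, which argues against a swapped label within the series and leaves a sample from outside it open. More seed-stage RNA in that sample was neither shown nor excluded: seed maturation genes lay above the other Col-0 arrays by a median of 0.22, 10 of 14 higher, where the upper end of the 95% range of random lists matched on level was 0.19. Against it, that median was under the bound of 0.3 set for ruling this out, and the mean of the list was higher in sco3 replicate 3 (3.48) and phyb replicate 3 (4.17) than in Col-0 replicate 3 (3.18), which correlated less with its group than these 2 arrays did (0.991 and 0.994). Yet 12 of the 14 genes were among the dimmest 40% of probe sets, where a rise is hard to see.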

How the results depend on the processing

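The alternatives named at the start were kept, and leaving out the neighbours of SCO3 was chosen only after the data were seen. No called result of a named gene reversed under the alternatives run for it, and no list test reversed with an estimated correlation, fry, the replicate block, a further quantile normalization, the dimmest probe sets left out or 1 array left out, the alternatives run for lists. List medians did turn with each array centred on its median, from 0.16 to -0.02 for the called glycosyltransferase list in sco3phyb against sco3 and from 0.10 to -0.02 in sco3phyb against Col-0. Of 8915 comparisons of 498 named gene results, 8252 kept the call and 663, in 119 of these results, lost it. Of 1085 comparisons of 64 gene list calls, 928 kept the call and 157 lost it. Apart from leaving out 1 array, the counts of called probe sets that moved by more than 1.5 times were 117 for sco3 against Col-0 with only the 2 genotypes fitted, and 6505 for sco3phyb against phyb and 1957 for the interaction with array weights. The causes were not tested. Fitting 2 genotypes alone also gave fewer calls for phyb against Col-0 (6198) and sco3phyb against Col-0 (5386). It gave more for sco3phyb against sco3 (7377) and sco3phyb against phyb (5018). Fewer arrays thus do not by themselves account for the 117. The 29 calls for fixed gene lists were 0 with camera at an estimated correlation, 38 with fry, and 23 both with the dimmest probe sets left out and after a further quantile normalization. Leaving out 1 array gave 396 to 1463 calls for sco3 against Col-0, 5958 to 8276 for phyb against Col-0, 5317 to 6964 for sco3phyb against Col-0, 5125 to 8030 for sco3phyb against sco3, 2218 to 4877 for sco3phyb against phyb and 661 to 1582 for the interaction. The slopes ranged from 0.346 to 0.456 and from 0.590 to 0.640, and the list calls from 22 to 35. With the replicate number as a block (replicate block), the counts were 888, 7408, 6527, 6410, 3204 and 1040, and 36 of the 90 tests of fixed lists were called. The shared numbers are not shown to be pairs: 4 of 12 arrays correlated best with their own number, and the 18 pairs had residual correlations from -0.274 to 0.150, 3 of them over 0.1. Without the neighbours of SCO3, 1075 probe sets were called in sco3. Signals near the lowest values on the arrays limit how far a fall can be followed.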

Other observations

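The lists of this part were chosen after the annotation was seen, seed maturation and branched-chain amino acid catabolism after the tests were seen. Genes of branched-chain amino acid catabolism were lower in phyb: MCCA fell by 4.02 ± 0.20, IVD (AT3G45300), the isovaleryl-CoA dehydrogenase, by 2.47 ± 0.16 and MCCB (AT4G34030) by 2.36 ± 0.16 on the log2 scale (standard error, n = 3, adjusted p from 4.05e-08 to 3.12e-07). Of 8 genes 7 fell (camera adjusted p = 2.12e-06, and adjusted p = 0.2 with an estimated correlation). In sco3phyb 6 of 8 fell against Col-0 (camera adjusted p = 1.05e-04, and adjusted p = 0.2 with an estimated correlation), and 3 rose against phyb (camera adjusted p = 2.75e-04, and adjusted p = 0.2 with an estimated correlation), MCCA by 1.95 ± 0.20 and IVD by 1.88 ± 0.16. Autophagy genes followed with 7 of 10 lower and 1 higher in phyb (camera adjusted p = 0.0035, and adjusted p = 0.425 with an estimated correlation). ATG8E (AT2G45170) fell by 2.37 ± 0.15 in phyb and rose by 0.89 ± 0.15 in sco3phyb against phyb, and the list had 7 of 10 lower and 1 higher in sco3phyb against Col-0 (camera adjusted p = 0.00674, and adjusted p = 0.465 with an estimated correlation, and 0.0604 without Col-0 replicate 3). Glucosinolate genes moved the other way, with 4 of 6 higher in phyb (camera adjusted p = 0.00309, and adjusted p = 0.203 with an estimated correlation) and 4 lower in sco3phyb against phyb (camera adjusted p = 3.15e-04, and adjusted p = 0.203 with an estimated correlation): BCAT4 rose by 3.72 ± 0.19 in phyb and GTR1 (AT3G47960), a glucosinolate transporter, by 1.66 ± 0.18. COR15A (AT2G42540) and COR15B (AT2G42530), induced by cold, rose by 3.64 ± 0.62 and 2.80 ± 0.51 in phyb, where 7 of 12 genes of that list rose (camera adjusted p = 0.00309, and adjusted p = 0.425 with an estimated correlation, and 0.112 with the dimmest 40% of probe sets left out). Tubulin genes had 5 of 7 higher and 1 lower in phyb (camera adjusted p = 0.00304, and adjusted p = 0.302 with an estimated correlation), TUB9 (AT4G20890) up by 1.17 ± 0.10, and 5 lower and 1 higher in sco3phyb against phyb (camera adjusted p = 0.00393, and adjusted p = 0.33 with an estimated correlation). M17 (AT2G41260), a seed maturation gene, rose by 2.83 ± 0.44 in phyb and fell by 2.27 ± 0.44 in sco3phyb against phyb, where 4 of 14 genes of its list fell (camera adjusted p = 1.63e-04, and adjusted p = 0.2 with an estimated correlation, and 0.0547 from fry). The mean of that list was uneven in phyb, at 3.17, 3.83 and 4.17 in replicates 1 to 3. Replicate 1 lay near Col-0 replicate 3 (3.18) and the sco3phyb arrays (2.91 to 3.04), so replicates 2 and 3 carried most of the change of the list. In phyb against Col-0 camera called this list at the preset correlation. The adjusted p was 0.428 with an estimated correlation, 0.0670 from fry and 0.0561 for camera without phyb replicate 3.

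Subunits of the nuclear RNA polymerases were higher in sco3phyb than in Col-0 for 9 of 12 genes, or 6 with each array centred on its median and 7 after a further quantile normalization (camera adjusted p = 4.83e-05, and adjusted p = 0.204 with an estimated correlation), with NRPA2 (AT1G29940) up by 1.56 ± 0.16. Cytosolic ribosomal protein genes had 40 of 86 higher in phyb, or 20 higher and 8 lower with each array centred on its median (camera adjusted p = 1.49e-08, and adjusted p = 0.465 with an estimated correlation), and 15 lower in sco3phyb against phyb (camera adjusted p = 2.79e-10, and adjusted p = 0.425 with an estimated correlation). In sco3 against Col-0 their median was 0.12 with 0 genes called. Camera called the list there, with an adjusted p of 0.72 at an estimated correlation and 0.0866 from fry. Among the glycosyltransferases, UGT84A3 rose by 3.98 ± 0.23 in sco3phyb against sco3, where 13 of 47 rose and 2 fell with a median of 0.16 that was -0.02 with each array centred, when 11 rose and 7 fell (camera adjusted p = 0.00758, and adjusted p = 0.27 with an estimated correlation). Expansin and xyloglucan endotransglucosylase genes had 11 of 28 lower and 1 higher in sco3phyb against phyb (camera adjusted p = 2.91e-05, and adjusted p = 0.203 with an estimated correlation), with XTH20 (AT5G48070) lower by 1.35 ± 0.15. The cell wall list is made of genes of these same families, so its fall there is not a separate result. Of the mitochondrial genes ccb452, for a protein of cytochrome c maturation, rose by 1.52 ± 0.19 in sco3phyb against phyb, where 3 of 15 rose (camera adjusted p = 0.0124, and adjusted p = 0.596 with an estimated correlation, 0.0945 without sco3phyb replicate 1, and 0.0614 from fry). Nuclear genes of thylakoid assembly and plastid RNA processing had 5 of 34 higher in sco3 (camera adjusted p = 3.14e-07, and adjusted p = 0.425 with an estimated correlation). OTP81 (AT2G29760), a plastid RNA editing factor, rose by 1.47 ± 0.14 in phyb. OTP81 and M17 lay below the lower quartile of every array in Col-0. bHLH121 (AT3G19860), 1 of 7 regulators of the iron response and a gene of the stretch around SCO3, fell by 1.27 ± 0.14 in sco3 and by 1.78 ± 0.14 in phyb, without a call for the list (camera adjusted p = 0.113 in sco3 and 0.642 in phyb). Among other families not called as lists in phyb, GSTU20 (AT1G78370) rose by 2.25 ± 0.36 among 11 tau glutathione transferases (camera adjusted p = 0.787), BGLU44 (AT3G18080) by 2.24 ± 0.24 among 20 beta-glucosidases (camera adjusted p = 0.729), CYP71B26 (AT3G26290) by 1.23 ± 0.14 among 18 cytochromes of that family (camera adjusted p = 0.106), and SWEET13 (AT5G50800) by 1.33 ± 0.17 among 14 sugar transporters (camera adjusted p = 0.441). The measured SAUR gene, AT2G18010, differed by 0.50 ± 0.19 in phyb without a call.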
